A study of Arabidopsis thaliana with 9 samples.

How the data were processed

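RNA from roots of 4-day-old Arabidopsis thaliana Col-0 seedlings was measured on 9 single-channel expression arrays, with 3 arrays for each of 3 genotypes: wild type, a bHLH49 mutant and a line that overexpresses bHLH49. The seedlings were grown on agar medium, per the labels' protocols, and the source label speaks of root tips while the tissue label speaks of roots. The labels number the arrays of a genotype as repeats 1 to 3 and do not say whether these came from separate batches of plants, so p-values measure the spread between these arrays, which may be partly technical.

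The authors deposited 1 table of log2 values, with 38408 probe sets on 9 arrays and 0 missing values. RMA, which corrects background, makes array distributions alike and summarises the probes of each set, is the only tool in the submitters' processing notes; its version and settings are not given in the sources used here. The 9 arrays had medians between 5.85 and 5.92 and maxima between 14.07 and 14.16, so the log2 values the authors deposited were taken as normalized between arrays and used as they stand. There is no read depth for arrays; their number limits the precision.

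Probe sets were named through the platform annotation given with the values and NCBI RefSeq genes of the assembly TAIR10.1, used only for names and for which genes neighbour each other. Of the 38408 probe sets, 16722 had exactly 1 gene, 759 had several and 20927 were not listed. Of the 16722, 16574 matched RefSeq by gene number and 148 kept the annotation's own name. Probe sets with several genes or none were tested but not named. No probe set of this annotation was paired with bHLH49 (AT1G68920), so its level was not analysed here and the genotype labels were not checked by it. The values of 5529 probe sets repeated those of an earlier probe set on all 9 arrays, of which 18 were named.

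Linear models were fitted per probe set to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual degrees of freedom and 1.85 prior degrees of freedom), so that the 3 genotypes shared an estimate of the spread. P-values were adjusted over all probe sets by the Benjamini-Hochberg procedure, and an adjusted p below 0.05 is what "rose", "fell" and "called" stand for. A moderated F test asked whether the 3 genotypes differed. Changes are log2 differences with the standard error (SE) of the fit; levels are means of log2 values with the standard deviation (SD).

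The genes named per comparison are the 10 with the largest rise and the 10 with the largest fall among called probe sets with 1 gene and no overlap between the arrays of both groups, along with members of fixed gene lists. Where fewer passed, all are given. This rule, the comparisons, the tests, 23 gene lists holding 428 genes and 30 words for gene families were fixed before the data were examined. The lists covered bHLH49 and its close relatives, HLH partners that do not bind DNA, early auxin response, auxin synthesis, transport and perception, embryo and root patterning, seed storage and embryo maturation, root hairs, epidermal fate, endodermis and suberin, xylem, phloem, root cap, photosynthesis as a marker of shoot tissue, cell cycle, wall loosening, brassinosteroids, cytokinin, iron deficiency, nitrate, jasmonate and wounding, immunity and camalexin, abscisic acid and drought, and flavonoids. Only 59 of the 428 genes had a probe set with 1 gene, and 9 lists had the 3 or more needed for a set test. Sets were tested with camera (preset correlation 0.01) against the 16722 probe sets with 1 gene, and again with the correlation estimated from the data; fry was an alternative. The family words were searched in gene symbols and synonyms, not in descriptions, so a family here holds only genes whose names contain its word. The word peroxidase found 10 genes, for instance, while 64 class III peroxidases were measured. Of the family words, 7 matched the 10 or more genes required. The family test was fixed in advance for both comparisons with wild type, and was added for overexpressor against mutant.

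Other splits of the arrays were counted, with all 10 splits of each pair of genotypes and 100 drawn splits of the 9 arrays. Because both comparisons with wild type share the same 3 wild-type arrays, 100 simulations of unchanged groups gave the correlation and covariance that sharing alone produces. On simulated data with the real means and spreads, in which 200 of 38408 probe sets were changed, the fit for overexpressor against wild type recovered 76.1% of 2-fold and 92.7% of 4-fold changes, and 4.69% of its calls were false. The corresponding values were 72.4%, 92.9% and 6.03% for mutant against wild type, and 74.2%, 93.4% and 6.05% for overexpressor against mutant.

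The alternatives tried were a block for the repeat number, eBayes with trend and robust, array weights, a fit to only the 6 arrays compared, quantile normalization again, arrays centred on their medians, filters at the 25th and 50th percentile of the mean log2 value, only probe sets with 1 gene, stricter thresholds, and leaving out each array in turn. Counting identical probe sets once and using all probe sets as the background of the set test were chosen after seeing the data, as were the alternatives for gene families in overexpressor against mutant. Figures were drawn with matplotlib 3.10.9.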

Results

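The arrays compared roots of 4-day-old seedlings that lacked normal bHLH49, overexpressed it, or were wild type, with 3 arrays each. bHLH49 is a basic helix-loop-helix transcription factor, and the series title places it in a study of auxin response in the embryo and suspensor. The overexpressor arrays stood apart in a principal component analysis, at 26.3, 25.9 and 36.3 on the component with 21.0% of the variance, while the other 6 arrays lay between -23.6 and -10.4. Pairs of arrays correlated across probe sets between 0.988 and 0.993. No probe set was paired with bHLH49 in the annotation used, so the change in its own transcript was not analysed here.

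Overexpression of bHLH49, compared with wild type, asked which root transcripts follow a gain of the factor. AT1G54870, a short-chain dehydrogenase, rose by 3.28 ± 0.15 on the log2 scale (SE), from 4.91 ± 0.21 in wild type to 8.19 ± 0.15 in the overexpressor (SD, n = 3; limma adjusted p = 0.000131). AT5G35870 rose by 3.29 ± 0.26 (adjusted p = 0.00204) and AT5G39493 by 2.85 ± 0.30 (adjusted p = 0.00518). AT5G39493 stood at 4.02 ± 0.62 in wild type, 5.81 in the mutant and 6.87 ± 0.20 in the overexpressor (SD, n = 3). AT5G35870 was dim in wild type, at 2.90, below the lower quartiles of the arrays (3.65 to 3.70). In the other direction scpl18 (AT1G33540), a serine carboxypeptidase-like protein, fell by 2.75 ± 0.11, from 6.59 ± 0.13 to 3.84 ± 0.17 (SD, n = 3; limma adjusted p = 9.88e-05). AT4G04760, a sugar transporter of the ERD6-like group, fell by 1.79 ± 0.15 (adjusted p = 0.0024).

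Among the other genes with large rises were AT2G16005, an ML-domain lipid-recognition protein (log2 change 2.02), the class III peroxidase gene AT2G18150 (1.96), AT5G01075 (1.94) and AT5G38000, a zinc-binding dehydrogenase (1.73). AT3G05770 rose by 1.70, and AT1G14120, a dioxygenase and paralogue of the auxin oxidase DAO1, by 1.63. AT2G25150, a BAHD-family acyltransferase, rose by 1.62. AT2G18150 was dim in wild type, at 3.05. The falls were smaller beyond the leading pair. AT5G25490, a zinc finger protein, fell by 1.54, and the neighbouring genes AT5G41290 and AT5G41300, both cysteine-rich repeat secretory proteins, fell by 1.52 and 1.44. AT1G69526 and the terpene synthase AT3G14540 each fell by 1.39, the polygalacturonase-like AT3G15720 and the cold- and abscisic acid-responsive KIN2 (AT5G15970) by 1.36, and the dioxygenase AT3G46500 by 1.33. The adjusted p-values of these 20 genes lay between 9.88e-05 and 0.0309.

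In all, 520 probe sets passed the test, 286 higher and 234 lower in the overexpressor, with a median absolute log2 change of 0.64. The majority turned among probe sets above the 50th percentile of the mean (413 higher and 465 lower), among those with 1 gene tested alone (216 and 221) and without overexpressor replicate 2 (83 and 91) or 3 (111 and 113). Of these, 262 had 1 gene (137 rose and 125 fell) and 258 were not named here. Changes of at least 2-fold were seen for 103 probe sets, 67 higher and 36 lower. The 3 overexpressor and 3 wild-type arrays did not overlap for 19.5% of all probe sets, where chance gives 10%. With 1 array left out, fewer probe sets passed: 191, 197 and 239 without wild-type replicate 1, 2 and 3, and 245, 174 and 224 without overexpressor replicate 1, 2 and 3. AT2G16005 and AT5G38000 missed the threshold in all 6 of these refits, AT2G18150 in 5 and AT2G25150 in 4.

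**Figure D1:**
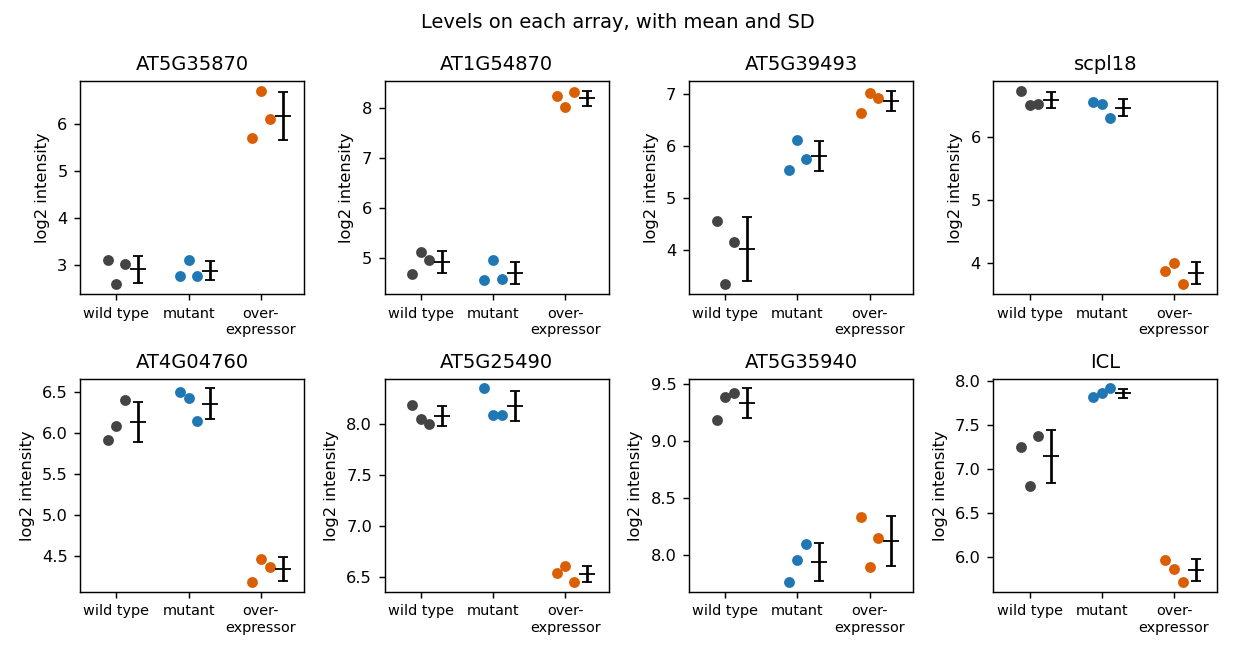
Log2 intensity (vertical axes, which do not start at 0) of 8 named genes on each of the 9 arrays, by genotype; points are arrays, and the bars beside them are the mean and SD of 3 arrays. The 3 overexpressor arrays lie apart from wild type in every panel, AT5G35940 is lower in both lines, at 7.94 in the mutant and 8.13 in the overexpressor against 9.33 in wild type, and ICL is at 7.87 in the mutant and 5.85 in the overexpressor.

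Early auxin response genes were higher in the overexpressor. Of 10 measured members 3 rose, 0 fell and 7 did not pass the test; adjusted over the list alone, 5 rose. GH3.3 (AT2G23170), which joins auxin to amino acids, rose 2.82-fold (SE 0.25 on the log2 scale, adjusted p = 0.0322). It stood at 7.10 ± 0.58 in wild type, 7.98 in the mutant and 8.59 ± 0.11 in the overexpressor (SD, n = 3). GH3.3 was not called between overexpressor and mutant. The related GH3.5 (AT4G27260) rose by 0.28 ± 0.05 on the log2 scale. LBD29 (AT3G58190), a LOB-domain factor of lateral root formation, rose by 0.88 ± 0.09 (adjusted p = 0.00518). The median log2 change of the list was 0.22 and camera called the list upward (adjusted p = 0.00037), but adjusted p = 0.0857 with an estimated correlation. LBD16 stood at 0.20 and GH3.1 at 0.24 without passing the test over all genes. The repressor genes IAA20, IAA29, IAA18 and IAA30 had changes of -0.10, -0.02, -0.05 and 0.08. Without 1 array, GH3.5 missed the threshold in all 6 refits and GH3.3 in 4.

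Wall-loosening genes, the expansins and the xyloglucan endotransglucosylase/hydrolases (XTHs), were also higher. Of 10 measured members 2 rose, 0 fell and 8 did not pass; adjusted over the list alone, 2 rose. These were the expansin EXPA4 (AT2G39700), by 1.00 ± 0.10 (adjusted p = 0.00498), and XTH20 (AT5G48070), by 1.05 ± 0.14 (adjusted p = 0.0154). XTH20 was dim, at 3.23 in wild type and 4.28 in the overexpressor, where the lower quartiles of the arrays lay between 3.65 and 3.70. The median change was 0.19, and camera called the list (adjusted p = 0.00282), but adjusted p = 0.202 with an estimated correlation. The call also ended without wild-type replicate 3 (adjusted p = 0.0941) and among probe sets above the 50th percentile of the mean (adjusted p = 0.108). XTH20 missed the threshold in 3 of the 6 refits without 1 array.

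Further list members changed in the overexpressor. RCPG (AT1G65570), a polygalacturonase of the root cap and the only measured member of its list, rose by 1.57 ± 0.15 (adjusted p = 0.00358). TRY (AT5G53200), a small MYB protein of epidermal cell patterning, fell by 0.85 ± 0.14 (adjusted p = 0.0323), a call lost in all 6 refits without 1 array. KIN2 was the 1 of 4 abscisic acid and drought genes that fell, 1 also adjusted over the list alone; the median of that list was 0.02 and its mean -0.26, while camera pointed downward (adjusted p = 0.627). The cytokinin response regulator ARR16 (AT2G40670) had a change of 1.26 ± 0.27 that missed the threshold (adjusted p = 0.082).

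The remaining lists held 0 calls in the overexpressor. The 4 root hair genes had a median change of -0.12 (camera adjusted p = 0.2; 2 fell adjusted over the list alone). The 5 bHLH relatives had a median of -0.01 (adjusted p = 0.627), the 3 auxin synthesis genes YUC2, YUC4 and YUC6 one of 0.12 (adjusted p = 0.627), and the 3 patterning genes BBM, LHW and JKD one of -0.07 (adjusted p = 0.469). For MCM7, AUR1 and AUR2 of the cell cycle list it was -0.09 (adjusted p = 0.627), and for 5 iron deficiency genes -0.02 (adjusted p = 0.627). In these last 5 lists 0 members passed adjusted over the list alone. Lists with 1 or 2 measured members gave values but no set test: the phloem gene SWEET11 stood at 0.84 ± 0.52 (0.19 without overexpressor replicate 3), the endodermal receptor SGN3 at -0.15, UPB1 at -0.27, PDF1.2 at -0.24 (-0.13 without overexpressor replicate 2) and DFR at -0.05 (-0.11 to 0.03 without 1 array, above 0 without overexpressor replicate 3). RCA and LHCB4.1, markers of shoot tissue, stood at 0.14 (0.08 without overexpressor replicate 3) and 0.00 (-0.08 to 0.09 without wild-type replicate 2 or 1), and 63 plastid-encoded genes had a median of 0.01 with 0 calls. For seed storage, xylem, brassinosteroid, nitrate and immunity genes 0 members had a named probe set. Of 7 gene families found by word, camera called 0; the smallest adjusted p, 0.154, was shared by the expansin and glycosyl hydrolase families.

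**Figure D2:**
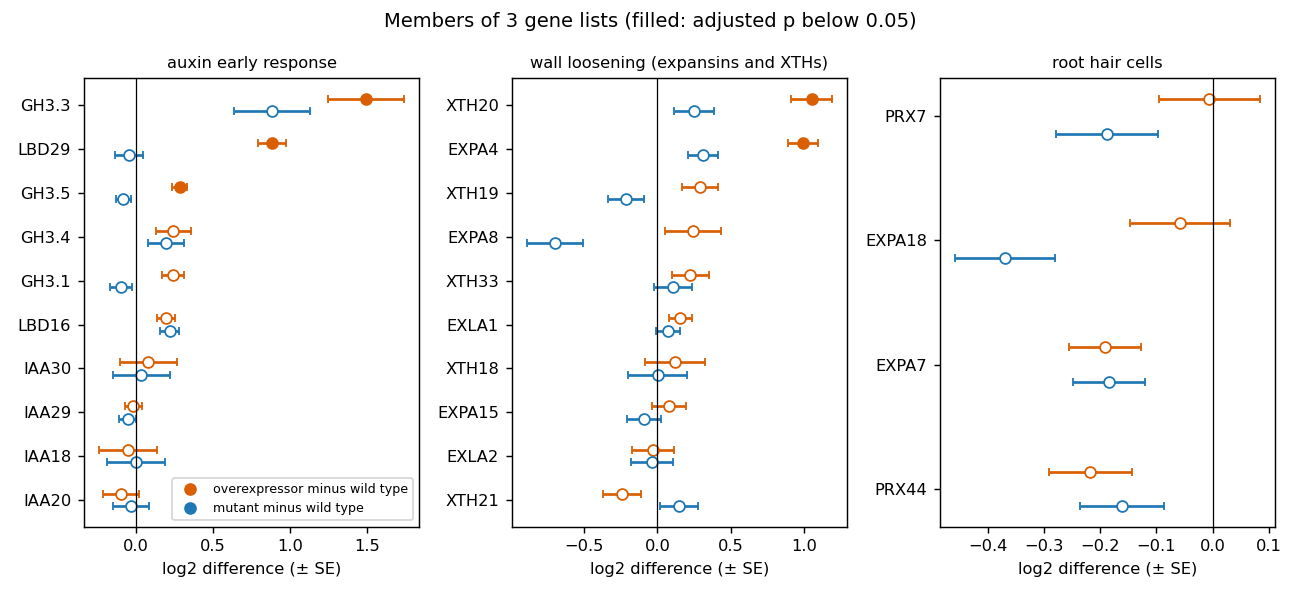
Log2 difference from wild type (horizontal axes, with SE) of the measured members of the early auxin response, wall-loosening and root hair lists in the overexpressor and the mutant, n = 3 arrays per genotype; filled points have an adjusted p below 0.05 over all probe sets. The overexpressor points of GH3.3, LBD29, GH3.5, XTH20 and EXPA4 are filled, and 0 mutant points are.

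The mutant compared with wild type asked which root transcripts follow the loss of normal bHLH49. AT5G35940, a jacalin-related lectin, was the only named gene to pass, falling by 1.39 ± 0.13 on the log2 scale (SE), from 9.33 ± 0.13 in wild type to 7.94 ± 0.17 in the mutant (SD, n = 3; limma adjusted p = 0.0318). It was lower on 3 of 3 mutant arrays, which the rule for naming genes required. The largest rise was of a probe set without a name here, 13381663, at 3.06 ± 0.10 (adjusted p = 9.26e-05). Probe sets given by number were chosen after their values were seen.

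In all, 9 probe sets passed, 6 higher and 3 lower, and 3240 had an unadjusted p below 0.05. With arrays centred on their medians, 11 passed, 6 higher and 5 lower, and among probe sets above the 50th percentile of the mean 13 passed, 3 higher and 10 lower. Because 3 of the 9 repeat the same values on all arrays, they stand for 7 distinct measurements. Arrays of both genotypes did not overlap for 12.4% of probe sets, where chance gives 10%. The count was 1, 2 and 6 without wild-type replicate 1, 2 and 3, and 1, 1 and 2 without mutant replicate 1, 2 and 3, and AT5G35940 missed the threshold in all 6. It also missed it with only the 6 arrays compared (adjusted p = 0.217; 0.0142 to 0.237 over its alternatives).

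Root hair genes were lower in the mutant as a list, though 0 of the 4 measured members passed over all genes and 2 fell adjusted over the list alone. The expansin EXPA18 (AT1G62980) stood at -0.37 ± 0.09, EXPA7 (AT1G12560) at -0.18 ± 0.06, and the peroxidases PRX7 and PRX44 at -0.19 and -0.16. The median was -0.19 and camera called the list downward (adjusted p = 0.0011), but adjusted p = 0.247 with an estimated correlation. The list held 16 genes, of which only these 4 had a named probe set. In the overexpressor, too, 0 of the 4 were above wild type (median -0.12), and camera did not call the list between both lines (adjusted p = 0.277). Part of the shared fall may come from the shared wild-type arrays. Of the markers of shoot tissue, LHCB4.1 stood at 0.27 ± 0.11 in the mutant (adjusted p = 0.594; 0.17 without mutant replicate 3) and RCA at 0.07 (-0.02 without mutant replicate 1), and the 63 plastid-encoded genes had a median of 0.06 (quartiles 0.01 and 0.12) with 0 calls, or 0.03 with arrays centred on their medians.

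The other 8 lists were not called in the mutant, and 0 of their members passed over all genes. The iron deficiency list had a median of 0.25 over 5 genes (adjusted p = 0.0861; 1 rose adjusted over the list alone), with S8H (AT3G12900), the scopoletin hydroxylase of iron-starved roots, at 1.90 ± 0.39 (adjusted p = 0.295). The iron deficiency list passed with arrays centred on their medians (adjusted p = 0.0399) and without wild-type replicate 1 (adjusted p = 0.0469). The list also passed without wild-type replicate 3 (adjusted p = 0.0391) or mutant replicate 3 (adjusted p = 0.0269). GH3.3 stood at 0.89 ± 0.25 and LBD16 at 0.22 ± 0.06, both counted as risen adjusted over the list alone; the auxin response list had a median of -0.02, a mean of 0.10 and an upward camera test (adjusted p = 0.734). RCPG stood at 0.63 ± 0.15 (adjusted p = 0.365). Wall-loosening genes had a median of 0.04 and a mean of -0.01, with an upward camera test (adjusted p = 0.734), with EXPA8 at -0.70 ± 0.19. The bHLH relatives, auxin synthesis, patterning, cell cycle and abscisic acid lists had medians of 0.00, -0.00, 0.01, -0.03 and -0.06, with adjusted p between 0.734 and 0.924 and 0 members passing adjusted over the list alone. For auxin synthesis and cell cycle the means, 0.04 and 0.03, and the camera test pointed upward against these medians. Of the 7 gene families camera called 0, the smallest adjusted p being 0.0699 for genes found by the word peroxidase.

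The overexpressor compared with the mutant set the 2 altered lines against each other. AT1G54870 was 11.3-fold higher in the overexpressor (SE 0.15 on the log2 scale; adjusted p = 8.1e-05), AT5G35870 was higher by 3.32 ± 0.26 (log2, SE) and AT2G25150 by 2.05 ± 0.24. AT4G33800, AT5G37620, AT3G30730 and AT1G16850 were higher by 1.91, 1.86, 1.80 and 1.65. Lower in the overexpressor were scpl18, by -2.62 ± 0.11, and ICL (AT3G21720), isocitrate lyase of the glyoxylate cycle, by -2.02 ± 0.14, with 5.85 ± 0.13 in the overexpressor against 7.87 ± 0.05 in the mutant (SD, n = 3; limma adjusted p = 0.00116). The germin-like AT5G38940 and the aldehyde dehydrogenase ALDH3F1 (AT4G36250) were lower by -1.38 and -1.31.

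AT2G16005, AT5G01075 and AT3G05770 were also higher than in the mutant, by 2.08, 2.05 and 1.66, and AT4G04760, AT5G41300, AT5G41290, AT5G25490, AT3G15720 and AT3G14540 were lower, by -2.01, -1.92, -1.83, -1.64, -1.46 and -1.29. In all, 702 probe sets passed, 373 higher and 329 lower in the overexpressor, 323 of them with 1 gene (174 higher and 149 lower) and 112 with at least a 2-fold change. With arrays centred on their medians the split was 458 higher and 251 lower, and it turned among probe sets above the 50th percentile of the mean (564 and 647) and with eBayes trend and robust (529 and 578). The count was 384 and 399 without mutant replicate 1 and 2, and 435, 295 and 307 without overexpressor replicate 1, 2 and 3. AT2G16005 missed the threshold in 5 and AT5G38940 in 4 of the 6 refits.

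Of 10 early auxin response genes 2 were higher in the overexpressor than in the mutant (LBD29, 0.93 ± 0.09, and GH3.5, 0.37 ± 0.05), 0 were lower and 8 did not pass, with 3 higher adjusted over the list alone. The median was 0.05 and the mean 0.22. Camera called the list upward (adjusted p = 0.00951), but adjusted p = 0.212 with an estimated correlation, and adjusted p = 0.0576 without mutant replicate 2. Wall-loosening genes, with a median of 0.15, were likewise called (adjusted p = 0.00674), but adjusted p = 0.212 with an estimated correlation; EXPA4 (0.68 ± 0.10) and XTH20 (0.80 ± 0.14) rose, and adjusted over the list alone 4 rose and 1 fell. That call ended among probe sets above the 50th percentile of the mean (adjusted p = 0.0825). Without 1 array, XTH20 missed the threshold in all 6 refits, EXPA4 in 3 and GH3.5 in 2. RCPG was higher by 0.94 ± 0.15, while TRY and KIN2 were lower by -0.82 and -1.09; RCPG and TRY each missed the threshold in 4 of these refits. The other 7 lists were not called, with adjusted p from 0.0756 for iron deficiency, where S8H stood at -1.64 ± 0.39 and 2 genes fell adjusted over the list alone, to 0.916 for auxin synthesis. Iron deficiency passed without mutant replicate 3 (adjusted p = 0.0352), without overexpressor replicate 2 (adjusted p = 0.03), with arrays centred on their medians (adjusted p = 0.0362) and with only the 6 arrays compared (adjusted p = 0.0452), and the patterning genes passed with fry, downward (adjusted p = 0.0466). The abscisic acid list had a median of 0.08 against a mean of -0.18 and a downward camera test (adjusted p = 0.768). LHCB4.1 stood at -0.27 ± 0.11 (-0.17 without mutant replicate 3), RCA at 0.07 (0.01 to 0.16 without overexpressor replicate 3 or mutant replicate 1) and the plastid-encoded genes at a median of -0.07 with 0 calls, or -0.03 with arrays centred on their medians.

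Of the 7 gene families found by word, camera called 3 upward in the overexpressor against the mutant. The family test had not been planned for this comparison. In both comparisons with wild type, where it had been planned, camera called 0 families. The 3 called were the genes named with the word expansin (2 of 25 rose, 0 fell, median 0.08, camera adjusted p = 0.00694), glycosyl hydrolase (1 of 19 rose, 0 fell, median 0.12, adjusted p = 0.008) or xyloglucan (2 of 11 rose, 0 fell, median 0.12, adjusted p = 0.0142). With an estimated correlation these became adjusted p = 0.0647, 0.0647 and 0.18. The expansin and xyloglucan families share members with the wall-loosening list.

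Across the 3 genotypes, 589 probe sets differed by the moderated F test. Leaving out wild-type replicate 1 and 2 gave 311 and 303, mutant replicate 2 and 3 gave 357 and 378, and overexpressor replicate 1, 2 and 3 gave 235, 189 and 202. The genes named above give its range of patterns: scpl18 stood at 6.59, 6.46 and 3.84 in wild type, mutant and overexpressor, AT5G39493 at 4.02, 5.81 and 6.87, and ICL at 7.14, 7.87 and 5.85.

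Loss and gain of bHLH49 were set side by side against the shared wild-type arrays. AT5G35940 fell in both lines, by 1.39 in the mutant and by 1.21 in the overexpressor (adjusted p = 0.00646). The probe set 13381663 rose in both, by 3.06 and 3.53, and 13416502 went opposite ways, at -0.80 in the mutant and 1.72 in the overexpressor. Of the 9 probe sets called in the mutant, 4 were higher in both lines (3 of them with identical values) and 1 was lower in both. A further 2, 13416502 and 13356803, were called in opposite directions. Independent lists of these sizes would share 0.0447 higher and 0.0183 lower probe sets, but lists that share wild-type arrays are not independent. Without 1 array, the mutant call of 13381663 was kept in all 6 refits. The mutant calls of AT5G35940, 13416502 and 13356803 were lost in all 6, and those of the 3 identical probe sets in 5. The overexpressor call of 13356803 was lost in 5. Over all probe sets the log2 changes of both lines correlated at 0.396, where genes are not independent replicates and shared wild-type arrays with no effect gave 0.501 (0.477 to 0.524 in 100 simulations). The covariance was 0.0214 against 0.0186 simulated (0.0173 to 0.0199), and 62.0% of probe sets had the same sign against 66.7% simulated. The simulated noise was independent between probe sets, so these ranges may be too narrow. The simulations also held no true changes, and true changes confined to either line would lower the correlation and the share of equal signs. A correlation and a share below the simulated values therefore do not show opposite effects. The covariance exceeded that of the shared arrays by 0.00286, an excess smaller than its SE of 0.0077 from leaving out each array in turn. Part of the overlap may come from the shared wild-type arrays, which are too few to divide into groups of 2.

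**Figure D3:**
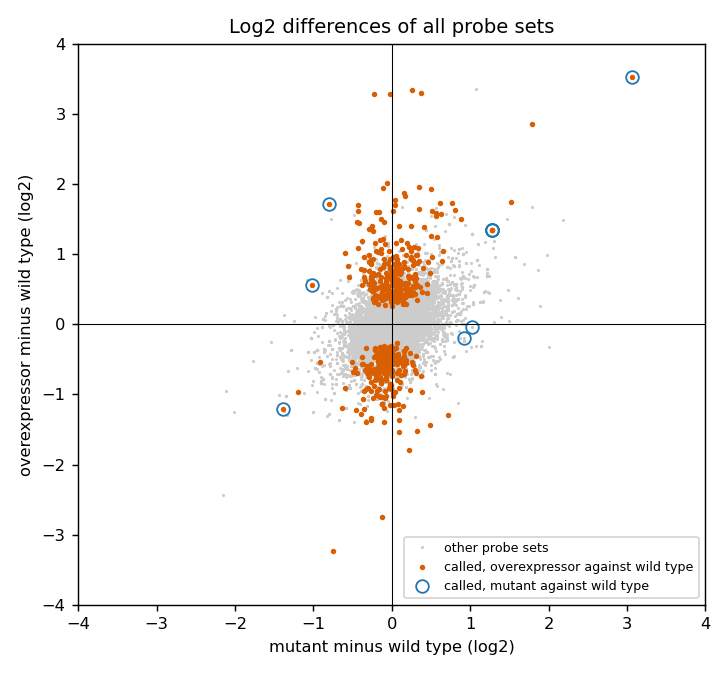
Log2 difference from wild type in the overexpressor (vertical) against that in the mutant (horizontal) for all probe sets; colour marks the 520 called in the overexpressor and open circles the 9 called in the mutant, 3 of which coincide. The called overexpressor changes spread mainly along the vertical axis.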

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

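The numbers of the arrays did not pair them: deviations of same-numbered arrays correlated between -0.09 and 0.03, and 2 of 9 arrays correlated best with their own number. With a replicate block, the calls were 200 for overexpressor against wild type, 1 for mutant against wild type, 347 for overexpressor against mutant and 259 among the 3 genotypes, and the counts of called lists and families were the same (0, 0 and 3 families). With eBayes trend and robust, these calls were 798, 11, 1107 and 903. With only the 6 arrays compared, they were 249, 2 and 260, and with the 50th percentile filter 878, 13, 1211 and 1011. With only probe sets that have 1 gene, 1 probe set was called in the mutant. An adjusted p below 0.01 left 140, 1 and 211; at least 1.5-fold left 293, 9 and 416; at least 2-fold left 103, 7 and 112, by construction. Array weights, both other scalings, the 25th percentile filter and, chosen after seeing the data, identical probe sets counted once (702, 10 and 878) moved these counts by less than 1.5 times.

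The 50th percentile filter turned the majority of calls: 413 higher and 465 lower for overexpressor against wild type, 3 and 10 for mutant against wild type and 564 and 647 for overexpressor against mutant. For overexpressor against wild type it also turned among probe sets with 1 gene (216 and 221) and without overexpressor replicate 2 (83 and 91) or 3 (111 and 113), for overexpressor against mutant with eBayes trend and robust (529 and 578), and for mutant against wild type among probe sets with 1 gene (0 and 1).

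Leaving out 1 array, which also leaves fewer samples, gave 174 to 245, 1 to 6, 295 to 510 and 189 to 400 calls, and 1 to 2 lists in overexpressor against wild type, 1 to 2 in mutant against wild type and 1 to 3 in overexpressor against mutant. Camera with the correlation estimated called 0 lists in each comparison. The estimates were 0.03 for the auxin response list, 0.11 for wall loosening and 0.27 for root hairs. This setting also raised p where the estimate was below the preset 0.01. For the expansin family in overexpressor against mutant, at -0.002, camera p went from 0.000991 to 0.0105. A call lost in this way thus does not by itself show that the genes of a set vary together. The 50th percentile filter called 1 list in overexpressor against wild type, 1 in overexpressor against mutant and 1 family, the expansins, in overexpressor against wild type (adjusted p = 0.0437) and in overexpressor against mutant (adjusted p = 0.00134), the only family that kept the 10 genes required; camera with the correlation estimated called 0 families in overexpressor against mutant. The alternatives for families in overexpressor against mutant were chosen after seeing the data. Centring on medians called 2 lists in mutant against wild type; centring on medians, only the 6 arrays compared and fry each called 3 in overexpressor against mutant. The cause was not tested. The covariance minus that of the shared arrays stayed positive, from 0.000324 to 0.0097. The genes named as largest rises and falls all kept their direction under these alternatives. With the replicate block, 3 of the 20 for overexpressor against wild type, 2 of the 20 for overexpressor against mutant and AT5G35940 in mutant against wild type (adjusted p = 0.186) missed the threshold; with only the 6 arrays compared, 3, 1 and again AT5G35940 (adjusted p = 0.217) did. Over all alternatives its adjusted p ran from 0.0142 to 0.237. The probe set 13342869, not called in overexpressor against wild type, ranged from -0.114 to 0.00384 without 1 array, changing sign without wild-type replicate 3. The list tests had no variant restricted to probe sets with 1 gene, since that is their background, and all probe sets as background, chosen after seeing the data, called the same number of lists. No alternative was run for the bHLH49 level, which was not analysed here. Background signal was not measured separately, so changes of dim probe sets are limited by an unknown floor.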

Other observations

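The groupings by gene family and by symbol, the neighbour test and the test of opposite directions in this part were chosen after the results were seen. Class III peroxidases, which act on cell wall polymers and reactive oxygen, held several rises in the overexpressor. Of 73 members of the family 64 were measured, and 6 rose, 0 fell and 58 did not pass the test. The rises were PRX15 (AT2G18150, 1.96 ± 0.32), PRX49 (AT4G36430, 1.61 ± 0.21), PRX62 (AT5G39580, 1.47 ± 0.17), PRX26 (AT2G43480, 0.61 ± 0.05), PRX11 (AT1G68850, 0.56 ± 0.08) and PRX22 (AT2G38380, 0.45 ± 0.08). Without 1 array, PRX11 missed the threshold in all 6 refits, PRX15 and PRX22 in 5, PRX49 in 4 and PRX62 in 1. PRX15 was dim in wild type, at 3.05. The median of the 64 was 0.01 and 35 were above 0. Camera gave p = 0.0147 upward with the preset correlation and p = 0.0809 with an estimated one, so whether the family rises as a whole stays open. PRX15, already among the 10 largest rises, stayed in this test, whose p is not adjusted for choosing the family after the results. Of the 10 genes found in advance by the word peroxidase, 0 rose and 1 fell (camera adjusted p = 0.293). Against the mutant 5 rose, 1 fell and 58 did not pass, with a median of -0.00 and a mean of 0.09 (camera p = 0.0557 upward, and p = 0.151 with an estimated correlation). That median was above 0 in quantile normalization again (0.01) and with arrays centred on their medians (0.03).

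Of 36 groups of genes that share a symbol stem, IQD genes, which encode calmodulin-binding proteins, had the smallest camera p in the overexpressor against wild type. The direction was downward (adjusted p = 0.000145, and adjusted p = 0.147 with an estimated correlation). Of 17 members 2 fell, IQD26 by 0.70 ± 0.07 and IQD16 by 0.47 ± 0.08, and the median was -0.16. The IQD16 call was lost in all 6 refits without 1 array. The 15 TRM genes, for TONNEAU1-recruiting motif proteins of the microtubule array, had a median of -0.11 with 0 calls. Camera gave adjusted p = 0.0107, and adjusted p = 0.147 with an estimated correlation, which at -0.009 was itself below the preset 0.01. The TRM genes were not called in overexpressor against mutant (camera adjusted p = 0.161), and their median in mutant against wild type was -0.06. Among 16 CLE peptide genes, CLE44 rose by 0.98 ± 0.07 (list adjusted p = 0.0107, and adjusted p = 0.326 with an estimated correlation). The stem GH holds 24 genes, of the GH9 cellulase family and the auxin-conjugating GH3 family, with a median of 0.06 (list adjusted p = 0.0107 upward, and adjusted p = 0.147 with an estimated correlation). The correlation estimated for these 24 genes was -0.012. Of these GH3.3, GH9C3 and GH9C2 rose, the GH9 pair by 1.04 ± 0.07 and 0.58 ± 0.09, and 21 did not pass; the GH9C2 call was lost in all 6 refits and that of GH3.3 in 4. Of 22 beta-glucosidase genes, BGLU21 fell by 1.02 ± 0.08, BGLU45 rose by 0.75 ± 0.11 (lost in 4 refits) and 20 did not pass (list adjusted p = 0.21). Of 33 SCPL genes scpl18, scpl22 and SCPL15 fell, the last 2 by 0.64 and 0.58 (lost in 3 and 6 refits), and 30 did not pass; the median was -0.01 (list adjusted p = 0.59). IQD and TRM medians stayed below 0 and the CLE median above 0 in quantile normalization again and with arrays centred on their medians.

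Among the 702 probe sets called between overexpressor and mutant, wild type lay between both lines for most: 75.5% had opposite changes against wild type. Choosing probe sets by the difference between both lines favours opposite changes, and no simulated share was set beside this one. Of the 520 called in the overexpressor against wild type, 63.7% had a mutant change of the same sign, which the shared wild-type arrays favour. Among the 702, wild type stood at a median of 0.23 of the way from mutant to overexpressor. Selection with a mutant equal to wild type gave at most 0.0418 in 100 simulations. These drew noise independently for each probe set and made a mean of 498 calls. Their range may therefore be too narrow to decide against selection of that kind. The 3 wild-type arrays alone gave 0.252, 0.265 and 0.178, so the position did not rest on 1 of them. Whether both lines oppose each other on balance stays open: the covariance of their changes exceeded that of the shared arrays by 0.00286, less than its jackknife SE of 0.0077. Selection of mutant changes unrelated to those of the overexpressor could produce the pattern. This was looked at among probe sets called in the overexpressor against 2 wild-type arrays, not among the 702. There the mutant went the opposite way from the held-out array in 45.5, 43.7 and 42.3% (lowest 42.3). The median mutant change along that of the overexpressor was 0.055, 0.057 and 0.036, slightly the same way. A biological opposition of loss and gain of bHLH49 at particular genes was not tested separately.

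Neighbouring named genes were called the same way in the overexpressor in 6 pairs, among them AT5G41290 with AT5G41300 (both lower) and AT2G43470 with AT2G43480 (both higher), and in opposite ways in 1 pair. In 10000 shuffles of the calls over 16348 genes the mean was 2.09 pairs and the highest 10 (permutation p = 0.0193). AT5G41290 and AT5G41300 had been seen among the largest falls before the test was chosen; without them 5 pairs stood against a mean of 2.04 and a highest of 9 (permutation p = 0.0532), so chance placement stays open. Tandem copies with similar sequence may share probes, and probe sequences were not used here, so this stays open too, beside shared regulation.

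For the counts of calls, 10 splits of 6 arrays are too few for a share below 0.05: the real split was 1 of 10, with 520 calls for overexpressor against wild type, 9 for mutant against wild type and 702 for overexpressor against mutant, and the highest of the other splits gave 0. For differences among the 3 genotypes, 1 of 100 splits of the 9 arrays, the real one, gave as many as 589 calls. The highest other gave 311. This argues against chance at this threshold but does not exclude it. Splits of arrays also cannot tell genotype from a difference between batches of plants.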
